A study of Homo sapiens with 8 samples.

How the data were processed

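RNA from OVCAR-3 cells, an established human ovarian carcinoma line, was profiled on 8 single-colour Illumina expression BeadChip arrays. Per the labels' protocols, cells in multiwell plates received siRNA against HBO1 or scramble siRNA, RNA was collected 48 h later with RNeasy columns, and biotin-labelled cRNA was made with the Ambion MessageAmp kit. The groups siHBO1 and siCTRL hold 4 arrays each, taken from the sample titles, which also number the replicates 1 to 4 in both groups. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples.

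The deposited non-normalized values are an intensity per probe and array on a linear scale. Their lowest value is 132 and their medians differ between arrays, so they carry the whole background and no normalization. A detection p-value per probe and array was deposited by the authors beside them, in steps of 1 in 770. Per the submitters' processing notes, GenomeStudio and lumi were used, and their versions, roles and settings are not given in the sources used here. The authors' processed values are on a log2 or similar variance-stabilised scale, which of these is not stated, and each column is a rising function of the same array's intensities (rank correlation 1). Sorted, these values differ by at most 0.00091 among the 6 arrays of replicates 1 to 3, and by up to 0.07 between those and both replicate 4 arrays, so the sorted values form separate sets. Their column medians are 6.57 for replicates 1 to 3 and 6.63 for replicate 4. They were used as an alternative, with their centring taken as it stands.

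The intensities of all 47312 probes were corrected with the nec function of limma 3.58.1 (normexp, with background parameters inferred from the detection p-values, offset 16), quantile-normalized and put on the log2 scale, in R 4.3.3 with the data.table package, version 1.17.8. The probe annotation supplied with the data pairs 30108 probes with a single gene symbol and 8 with several, and lists none for 17196. Of these probes, 30069 matched a gene of the RefSeq annotation of GRCh38.p14 by Entrez identifier and 0 symbols changed. That annotation served for names only, since the build behind the array is not stated, and no coordinates are given. Probes with a detection p under 0.05 on at least 4 of the 8 arrays were kept, which left 21377. A gene was its kept probe with the highest mean level. Of 17297 genes tested, 12222 carry a gene symbol and 5075 are probes without a listed symbol, tested under their own ID. Several kept probes stood behind 3273 genes.

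On the 8 arrays the median intensity ran from 224 to 324 and the number of detected probes from 20504 to 22111, which is 43.3% to 46.7% of all probes. Pearson correlations of the log2 non-normalized intensities over all probes lay between 0.982 and 0.997 for any pair of arrays, so no array was a copy of another. Within a group they were 0.984 or above. The number of arrays limits the precision. No slide or scan date is named in the files used here.

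The groups were compared gene by gene with lmFit and eBayes of limma, as siHBO1 minus siCTRL, 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Gene lists with at least 5 tested members, 27 of the 28 written before the data were examined, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 27 lists. Of 698 list symbols, 3 had no match. Members were also counted after adjustment over the list alone. List means per array were compared with an exact 2-sided permutation test, which for 4 against 4 arrays cannot go below 0.0286.

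The replicate numbers are those of the labels, which do not say what a number shares. Across genes, deviations from the group means correlated between same-numbered arrays at r = 0.783, 0.324, 0.397 and 0.217 for replicates 1, 2, 3 and 4; genes are not independent replicates. Each is over 0.1, so the numbers were taken as pairs. For replicates 2 to 4 that bound does not single out a pair, since an array of another number correlated more highly. The highest such values were 0.404, 0.404 and 0.383, against 0.324, 0.397 and 0.217 for the same number. The pairing behind the block is thus borne out for replicate 1 only. The first principal component held 58.2% of the variance and set both replicate 1 arrays apart from the other 6. The fit without a block was the main one, and the fit with the replicate number as a block was planned beside it.

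Genes were named by a rule written before the data were examined: KAT7 and the tested members of its complexes, the 12 largest rises and 12 largest falls among genes past the threshold whose groups lie fully apart, and for each list up to 4 members past the threshold, or up to 2 with the smallest p, as values only. Probes without a listed symbol and pseudogenes were left out of the rises and falls, 1 without the block and 8 with it. Applying the rule to the blocked fit as well was decided after the data were seen.

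The procedure was tested on simulated values for the same comparison with 17293 genes. Without the block it recovered 39 of 64 genes changed by 1 on the log2 scale, 57 of 61 changed by 2 and 0 of 65 changed by 0.5, with 2 false calls. With the block it recovered 56 of 64, 58 of 61 and 0 of 65, with 3 false calls. The simulated values held replicate effects, so the higher recovery with the block cannot tell whether the block is right for the real arrays. These counts were not split by signal level, so they do not give the power for dim probes. A simulated list of 29 genes was called by each list test, and camera with the preset correlation also called 1 list that had not been changed. Beyond the replicate effects, noise was drawn for each gene independently. The list tests were thus not tried on genes that vary together, as in the interferon list, whose estimated correlation was 0.57. Alternatives to the background correction, offset, normalization, probe filter, probe choice, variance model, array weights, block and threshold were planned, as was leaving out each array. Leaving out each replicate number in both groups, and the authors' values with the block, were added after the data were seen.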

Results

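The series profiled mRNA in OVCAR-3, a human ovarian carcinoma cell line, after transfection with siRNA against HBO1. HBO1, whose gene symbol is KAT7 and older symbol MYST2, is the catalytic subunit of histone acetyltransferase complexes. RNA was taken 48 h after transfection with HBO1 siRNA (siHBO1, 4 arrays) or scramble siRNA (siCTRL, 4 arrays). Between 20504 and 22111 probes were detected per array, and 17297 genes or unnamed probes entered the comparison. The comparison asks which transcripts differ between cells given HBO1 siRNA and cells given control siRNA.

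KAT7, the targeted gene, was measured by 1 probe, ILMN_1798187. Its normalized log2 intensity was 7.67, 7.97, 7.93 and 7.35 on siCTRL replicates 1 to 4. On siHBO1 replicates 1, 2 and 3 it was 6.66, 6.86 and 7.04. The array labelled siHBO1 replicate 4 stood at 7.43, within the range of the siCTRL arrays and 0.08 above siCTRL replicate 4, the lowest of them. The differences in the other numbered pairs were -1.01, -1.10 and -0.89. Over all 8 arrays, the array labelled siHBO1 replicate 4 included, the log2 fold change was -0.73 (SE 0.19, 95% confidence interval -1.16 to -0.30, n = 4 each), or 1.66-fold lower. This did not pass the test over all genes (limma adjusted p = 0.586, and 0.381 with the replicate block), and an exact 2-sided permutation test of the 4 against 4 arrays gave p = 0.0571. Detection p-values of the probe ran from 0.0013 to 0.0208, so it was a dim probe detected on every array.

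No measured partner of KAT7 in its complexes passed the test. The listed partner BRD1 had no probe under its symbol and was not measured. The scaffold proteins BRPF1, BRPF3 and JADE1 had log2 fold changes of 0.04, 0.03 and -0.02, JADE2 and JADE3 of 0.22 and 0.10, and the reader proteins ING4 and ING5 of -0.01 and 0.05. MEAF6 stood at -0.19 on 1 probe and 0.25 on another, so its probes disagreed in sign, and the 95% confidence intervals of ING4 (-0.62 to 0.60) and MEAF6 (-0.80 to 0.42) were wide. None of the 9 members tested passed over all genes, and adjusted over the list alone 1 passed, KAT7, with 0 passing under the block. The list as a whole did not pass (camera adjusted p = 0.998), with a median of 0.03 and a mean of -0.06 of opposite sign. Among other lysine acetyltransferases, EP300 stood at 0.30 and KAT2B at -0.27, with 0 of 11 members past the threshold (median 0.05, adjusted p = 0.827).

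**Figure D1:**
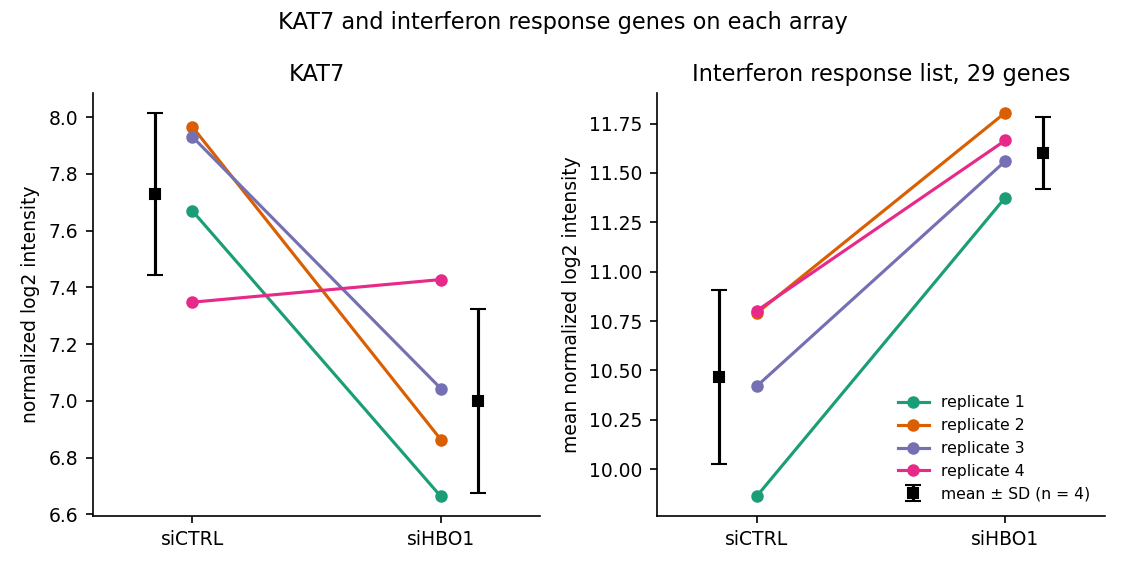
Normalized log2 intensity of KAT7 (left) and the mean over the 29 tested interferon response genes (right) on each array, with a line joining arrays of the same replicate number and black squares for the group mean ± SD (n = 4). KAT7 lies at 7.43 on the array labelled siHBO1 replicate 4, while the interferon mean is between 11.38 and 11.80 on the siHBO1 arrays and between 9.86 and 10.80 on the siCTRL arrays.

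Interferon-stimulated genes were higher in the siHBO1 group. CXCL10, a chemokine that attracts T cells, rose by 1.76 on the log2 scale (SE 0.22, 3.39-fold). RIGI, a cytosolic sensor of viral RNA, rose by 1.10 (SE 0.12). The transcription factor IRF7 rose by 0.97 (SE 0.11), the ADP-ribosyltransferase PARP14 by 0.89 (SE 0.11) and the chemokine CXCL11 by 0.89 (SE 0.11). By the naming rule each was higher on all 4 siHBO1 arrays than on any siCTRL array, the array labelled siHBO1 replicate 4 included. Each had a limma adjusted p of 0.0442. CXCL11 was detected on only 3 of the 4 siCTRL arrays and its rise ran from 0.38 to 1.02 over the alternatives, so its size is uncertain. The 1 transcript that fell was an unnamed probe, ILMN_3274914, at -1.44 (SE 0.17, 2.71-fold lower, adjusted p = 0.0442).

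In all, 6 of 17297 genes passed the threshold, 5 higher and 1 lower, and 655 had an unadjusted p under 0.05. With the replicate block 58 passed, 47 higher and 11 lower, among them the same 6. The count without the block was 0 when siCTRL replicate 2, 3 or 4 or siHBO1 replicate 2, 3 or 4 was left out (limma, with 508 to 659 genes at an unadjusted p under 0.05), and 5 without either replicate 1 array. With the block it was 4 without replicate 1 in both groups, 0 without replicate 2 or replicate 3 (1068 and 1089 at an unadjusted p under 0.05) and 33 without replicate 4, whose arrays form a separate set in the authors' processed values. Groups lay fully apart for 488 genes, which is 2.82% of those tested. Chance gives 2.86% if all 8 arrays are exchangeable, which the shared deviations of the replicate 1 arrays (r = 0.783) speak against. The other 7 splits that part every pair gave 134 to 555 genes.

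The blocked fit added further genes that rose. OAS2, an enzyme that makes the activator of RNase L, rose most among the named genes, by 2.58 (block SE 0.15, adjusted p = 0.00445 with the block and 0.146 without). The restriction factor TRIM22 rose by 2.07 (block SE 0.21, adjusted p = 0.0229), IFI44L by 1.86 and the lysosomal transporter SLC15A3 by 1.81. OAS2, TRIM22 and SLC15A3 were detected on only 3 of the 4 siCTRL arrays, so the size of their rises is uncertain. Over the alternatives the rise ran from 1.74 to 2.86 for OAS2, 1.29 to 2.30 for TRIM22 and 0.94 to 2.00 for SLC15A3. IFITM1, which hinders virus entry, rose by 1.74, IFI27 by 1.70, RSAD2 (viperin) by 1.64 and BST2 (tetherin), which holds back budding virions, by 1.54. IFIT3 and DDX60 rose by 1.48 and 1.41, and SAMD9L by nearly as much. All of these were higher in every numbered pair, which the naming rule guarantees, since it takes only genes whose groups lie fully apart. They passed in the blocked fit, at adjusted p between 0.00445 and 0.0384, and not in the main fit. Some also passed under other settings without the block: over all alternatives BST2 passed in 11 of 32 and OAS2 in 6 of 31. Other kept probes of OAS2, IFI44L and IFIT3 gave log2 fold changes of 2.42, 1.66 and 1.59 to 1.99.

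The named genes that fell with the block were 7, each lower in all 4 pairs, as the naming rule guarantees. SMPDL3B, a membrane phosphodiesterase, fell by 1.08 (block SE 0.09, adjusted p = 0.0155), though its other kept probes gave -0.81 and 0.15. CA12, a membrane carbonic anhydrase induced by oestrogen receptor, fell by 0.97 (block SE 0.09, adjusted p = 0.0185). The peptide hormone gene EDN2 fell by 0.87, the neuropeptide receptor gene NPFFR2 by 0.85 and the glycosyltransferase gene EOGT by 0.85, with other probes of NPFFR2 and EOGT at -0.56 and -0.31. The cochaperone gene CHORDC1 fell by 0.66 and the keratin gene KRT4 by 0.63. None of the 7 passed in the main fit without the block, where EOGT came nearest (adjusted p = 0.0581). Some passed under other settings without the block, as EOGT did, which passed in 9 of 32 alternatives in all.

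**Figure D2:**
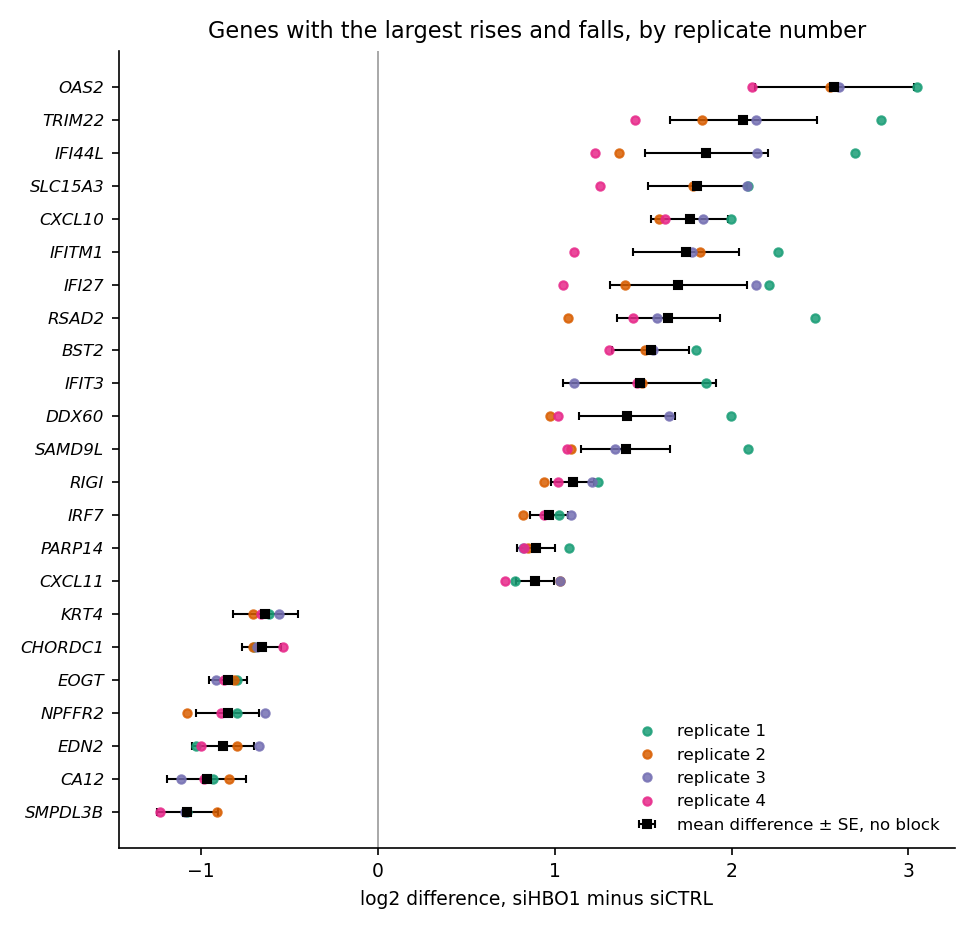
Log2 difference between siHBO1 and siCTRL arrays of each replicate number (coloured points) for the 16 named genes that rose and the 7 that fell in either fit, with black squares for the mean difference and bars for its SE without the block. All 4 points of every gene lie on one side of 0, because only genes whose groups lie fully apart were chosen. They run from 2.12 to 3.05 for OAS2 and from -1.23 to -0.91 for SMPDL3B.

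The interferon response list, which gathers genes induced by interferon together with antigen-processing genes, rose as a group by camera with the preset correlation, a call lost with an estimated correlation (adjusted p = 0.105, or 0.422 with the block). Of 29 members measured, 3 rose over all genes tested (CXCL10, RIGI and IRF7), 18 with the block, and 25 adjusted over the list alone (26 with the block). All 29 log2 fold changes were positive, with a median of 1.18 and a range of 0.05 to 2.58, and 26 members were higher in every numbered pair. The pair medians were 1.62, 0.94, 1.21 and 0.94. The last of these belongs to the array labelled siHBO1 replicate 4, where KAT7 was not lower. IFIT1 at 2.03, ISG15 at 1.42 and MX1 at 0.82 passed over the list alone, whereas IFI6 at 0.05, IRF1 at 0.14 and XAF1 at 0.15 did not.

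The list shift had a camera adjusted p of 6.7e-60 with the preset correlation, and adjusted p = 0.105 with an estimated correlation (0.422 with the block). The fry test of a movement in one direction gave an adjusted p of 0.0422, or 0.0464 with the block, and it did not pass under median scaling (0.179), with no normalization (0.915) or with the authors' values (0.0544). It also did not pass without siCTRL replicate 2, 3 or 4 (0.0751, 0.156 and 0.0596) or without siHBO1 replicate 1, 2, 3 or 4 (0.0955, 0.168, 0.130 and 0.111). The list mean was 11.60 ± 0.18 in siHBO1 and 10.47 ± 0.44 in siCTRL (SD, n = 4 each), and the exact permutation p of 0.0286 is the smallest that 4 against 4 arrays allow (0.386 adjusted over the lists). The lowest list mean, 9.86, belonged to siCTRL replicate 1, 1 of the arrays that the first principal component set apart, and without both replicate 1 arrays the median was 1.07. Within replicates 1 to 3 alone, leaving out the set that the authors' values keep apart, the camera adjusted p was 2.56e-51 (0.360 with an estimated correlation, and 0.212 by fry).

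Inflammatory genes under NF-kB and replication-dependent histone genes shifted upwards as lists by a small amount. The NF-kB list had a median of 0.12 over 18 members (camera adjusted p = 0.0236, and adjusted p = 0.474 with an estimated correlation). Its members CCL20, a chemokine, and ICAM1, an adhesion molecule, stood at 0.51 and 0.37, TNFAIP3 at 0.36, and 0 members passed over all genes or adjusted over the list alone (1 over the list alone with the block, CCL20). The histone list had a median of 0.12 over 13 members (camera adjusted p = 0.0236, and adjusted p = 0.657 with an estimated correlation), with H2AC20 at 0.25, H2AC6 at 0.23, H3C4 at 0.31 and 0 members past either adjustment. Neither list passed fry (adjusted p = 0.385 and 0.567). The adjusted p of the NF-kB list was 0.136, 0.125 and 0.106 without siCTRL replicate 2, 3 or 4, and 0.268 and 0.0614 without siHBO1 replicate 1 or 3. That of the histone list was 0.155, 0.187 and 0.0925 without the same siCTRL arrays, and 0.268 and 0.0899 without siHBO1 replicate 1 or 2.

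YAP and TAZ target genes and components of the Hippo pathway, which controls those coactivators, passed no test of a shift in one direction. The targets had a median of -0.05 over 20 members (camera adjusted p = 0.949), with 0 past the threshold. The receptor tyrosine kinase gene AXL stood at -0.68 (SE 0.18, adjusted p = 0.609, other probe -0.28) and the ectonucleotidase gene NT5E at 0.48 (adjusted p = 1.00). Adjusted over the list alone, 0 passed without the block and 2 with it, AXL lower and NT5E higher. In the Hippo list, with 19 members and a median of -0.01 (adjusted p = 0.998), YAP1 stood at -0.47 (SE 0.12, adjusted p = 0.575), FAT4 at 0.31 and TEAD1 at 0.27, and 0 passed over the list alone.

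Lists of the cytoskeleton, adhesion, matrix and caveolae passed neither camera nor fry in one direction. Actin cytoskeleton genes had 0 of 41 members past the threshold, with LIMK2 at 0.26 and MYL9 at -0.26; the median of -0.01 and mean of -0.00 were of opposite sign to the test (adjusted p = 0.998). Focal adhesion and integrin genes had 0 of 34, with ITGA1 at 0.41 and ITGA5 at -0.35, and a median of 0.00 and mean of 0.01 against a test pointing down (adjusted p = 0.998). Among 24 extracellular matrix genes (median 0.00, adjusted p = 0.947), LOX, a collagen crosslinking enzyme, stood at 0.70 and PLAU, the urokinase gene, at -0.48. These passed when adjusted over the list alone, 1 higher and 1 lower, and with the block COL12A1 joined them at 0.54. Caveola genes had a median of -0.02 over 16 members (adjusted p = 0.443), with CAVIN1 at -0.35 and CAV2 at -0.28.

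Markers of epithelial identity did not pass, as single genes or as a list. EPCAM stood at 0.15, GRHL2 at -0.15 and MUC1 at 0.15, with 0 of 27 epithelial markers past the threshold (median 0.01, adjusted p = 0.998). Of 20 mesenchymal markers 7 were tested, with SPARC at -0.28, S100A4 at -0.19, TWIST1 at 0.28 and a median of 0.15 (adjusted p = 0.827). Of the 12 hormone receptors and targets, CA12 fell with the block and over the list alone, and MYB stood at 0.33 and passed over the list alone with the block. That list did not move one way (median -0.02, adjusted p = 0.827), while fry's test for change in either direction gave an adjusted p of 0.0038, the other list under 0.05 being the interferon list at 0.00773. With the block 9 of 27 lists passed that test: these at 0.000187 and 0.00488, NF-kB genes and extracellular matrix genes at 0.00209, YAP/TAZ targets at 0.00488, Hippo components, mesenchymal markers and cholesterol genes at 0.00504, and caveola genes at 0.0230.

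Genes of the cell cycle and of cell death passed no list test over all 8 arrays. Replication licensing genes, whose products load and fire origins, had a median of 0.02 over 25 members (adjusted p = 0.827), with GINS3 at 0.17 and CDC6 at 0.28. S-phase genes had a median of 0.04 over 29 (adjusted p = 0.290), with CCNE1 at 0.27 and E2F1 at -0.45, and genes of mitosis a median of -0.03 over 31 (adjusted p = 0.827), with AURKA at -0.24 and KIF20A at -0.25. The p53 targets PHLDA3 and TP53INP1 stood at -0.28 and 0.25, SESN2 at -0.21, and the list of 19 had a median of 0.00 and a mean of -0.01, the mean against a test pointing up (adjusted p = 0.998). Apoptosis regulators had a median of -0.03 over 23, also against a test pointing up (adjusted p = 0.998), with APAF1 at 0.26 and XIAP at 0.17. Leaving out siCTRL replicate 1 put the mitosis list past the threshold (median -0.07, camera adjusted p = 0.0369). Leaving out siHBO1 replicate 1 did so for the S-phase list (median 0.13, camera adjusted p = 0.0192). Each list passed in only 1 of 34 alternatives, so neither passed when both replicate 1 arrays were left out. No member of these 5 lists passed over all genes or adjusted over the list alone.

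No metabolic or stress list passed camera or fry in one direction, apart from ribosomal protein genes by camera under other scalings. Cholesterol and lipid synthesis genes had a median of -0.06 over 23 members (adjusted p = 0.290), with LSS at -0.42, MVK at -0.20 and ELOVL6 at 0.19; LSS alone passed over the list alone, with the block. Of these genes 18 were negative, and the list mean was lower in siHBO1 in every pair (11.07 ± 0.04 against 11.13 ± 0.02, SD, n = 4 each), with the smallest exact permutation p possible, 0.0286 (0.386 adjusted over the lists). Glycolysis and hypoxia genes had a median of 0.01 over 25 (adjusted p = 0.827), with EGLN3 at -0.42, HK2 at 0.33 and PFKP at 0.34. Oxidative phosphorylation genes had a median of 0.02 over 29 (adjusted p = 0.303), with NDUFA1 at 0.20 and NDUFS1 at 0.41. Unfolded protein response genes stood at a median of 0.01 over 20 (adjusted p = 0.998), with ASNS at -0.15 and DNAJC3 at 0.15. Ribosomal protein genes had a median of -0.05 over 31 (adjusted p = 0.158), with RPL30 at -0.25 and RPL37 at -0.42, where another RPL37 probe gave 0.01. Under median scaling this list passed at a median of -0.14 (adjusted p = 6.86e-06), and with no normalization at -0.18 (adjusted p = 1.5e-07). Immediate early and heat shock genes had a median of 0.05 over 23 (adjusted p = 0.158), with FOSB at 0.27 and JUNB at 0.41, the latter passing over the list alone with the block.

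Of 27 lists, 8 had a mean higher in siHBO1 in every pair and 3 lower. Chance gives 12.5% of lists for both directions together, if the pair differences are independent and as likely up as down. Lists on the same arrays can move together, so their count may stray further from that share. The higher ones were interferon, NF-kB, histone, mesenchymal, S-phase, glycolysis, oxidative phosphorylation and immediate early genes, and the lower ones caveola, cholesterol and ribosomal protein genes.

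Markers of other cell types were mostly undetected. Of the 20 leukocyte markers 6 were tested, with AIF1 at -0.20 and CD79A at -0.10 (median -0.01, adjusted p = 0.827). Of 16 fibroblast markers 5 were tested, with FBLN2 at -0.18 and PRRX1 at -0.13 (median -0.09, adjusted p = 0.290). Among 14 endothelial markers 2 were measured, too few for a list test, with VWF at -0.34 and EGFL7 at 0.08. No marker of these lists passed over all genes or adjusted over the list alone.

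**Figure D3:**
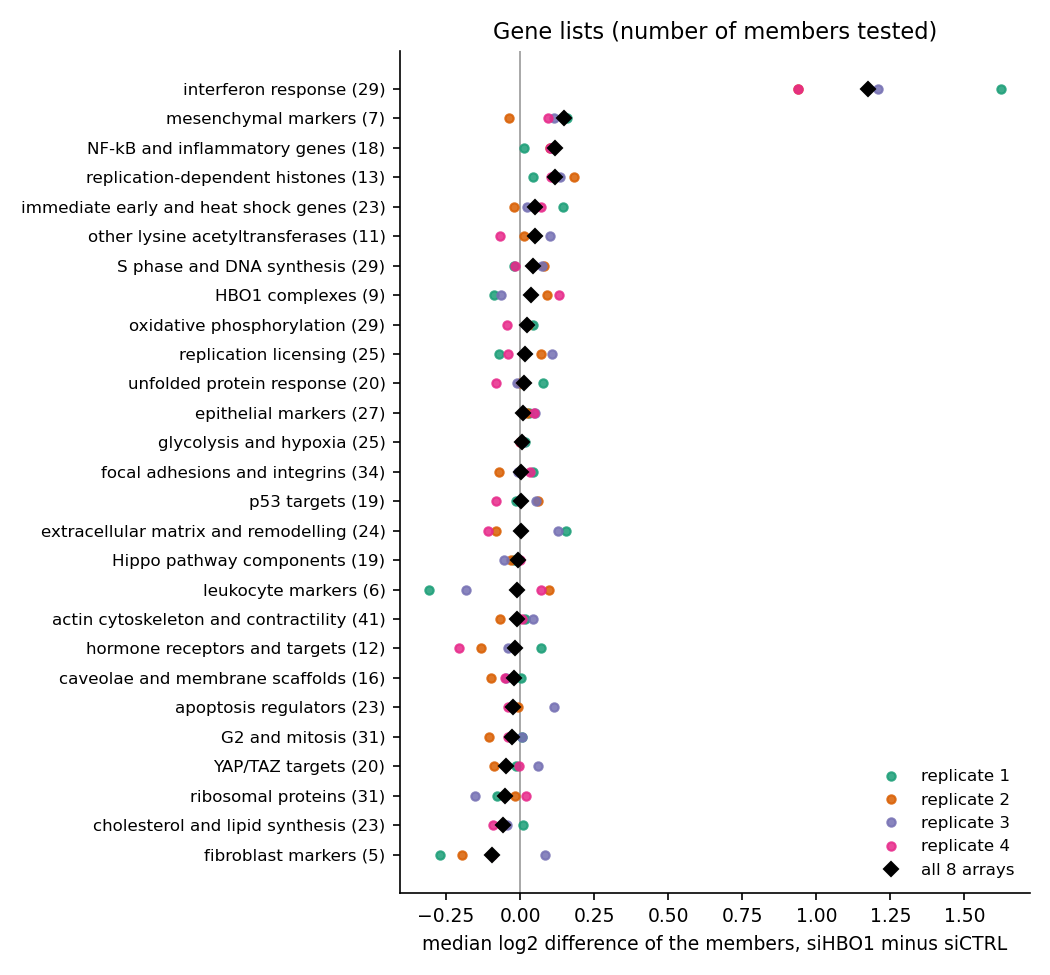
Median log2 difference between siHBO1 and siCTRL over the tested members of each of 27 gene lists, for all 8 arrays (black diamonds) and for each replicate number (coloured points), with the number of members tested in brackets. The interferon response list lies at 1.18, and its pair medians lie between 0.94 and 1.62; the medians of the other lists lie between -0.09 and 0.15.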

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

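In this part the tests of a wrong label, of RNA from other cell types, of noise on the replicate 1 arrays and of noise of the KAT7 probe were chosen only after the result was seen, as were the interval of the ratio and the strata of level used for the replicate 1 arrays. Of 242 groups of 4 arrays examined, 26 held an array far from its 3 neighbours, its gap to the nearest being a larger part of the range than Dixon's 95% critical value; chance alone singles out about 1 in 20 groups. Of these, 12 were on siCTRL replicate 1 and 5 on siHBO1 replicate 1, and 3 each on siCTRL replicate 4 and the array labelled siHBO1 replicate 4.

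On siCTRL replicate 1 the median intensity was 224, against 305 to 312 on the other siCTRL arrays. There MEAF6 was 7.53, GRHL2 8.59, IFIT3 8.92 and KRT4 8.49, each below the other siCTRL arrays, and CCNE1 13.22 and EOGT 9.82, above them. The list means of S phase (10.96), mitosis (11.94) and hormone targets (9.93) were low on that array, and those of NF-kB genes (10.35) and the unfolded protein response (11.40) high. On siHBO1 replicate 1 the means of YAP/TAZ targets (10.47), epithelial markers (11.80) and the unfolded protein response (11.51) were high, and that of replication licensing (10.88) and the level of MVK (7.23) low. Replicate 4 of siCTRL had ASNS at 13.42 and TNFAIP3 at 10.34, both low, and ELOVL6 at 12.85, high. The array labelled siHBO1 replicate 4 had E2F1 at 7.41 and RPL30 at 14.13, both low, and EDN2 at 8.32, high. Single values stood apart for NT5E on siCTRL replicate 3 (8.63, low), FOSB on siHBO1 replicate 2 (8.23, high) and SAMD9L on siHBO1 replicate 3 (8.39, low).

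Both replicate 1 arrays shared a pattern: 351 genes lay at least 1 log2 unit above the other 6 arrays on both, and 9 as far below, with ABRAXAS1 3.44 and MIGA1 3.33 above on average. Noise of dim probes is argued against, since 0 genes stood as high on both arrays in any of the other 27 pairs of arrays, and the arrays taken separately give 12.6 shared genes within 10 strata of level. Over 5 fibroblast markers the median shift was -0.0052 (SD 0.27), from -0.18 for PRRX1 to 0.52 for COL1A1. Only markers detected on at least 4 arrays were tested, so a marker present on the replicate 1 arrays alone would have been left out. RNA of fibroblasts thus stays open. That of leukocytes is argued against by a median of 0.020 over 6 (SD 0.89), with PTPRC, LYZ and TYROBP detected on 0 arrays, although CD68 stood 2.10 higher and the list mean was highest on these arrays (8.74 and 8.56, against 8.19 to 8.34). For endothelial cells 2 markers, with a median of -0.0032, are too few to tell. Scaling stays open. The pattern held at 340 higher and 10 lower with median scaling, 245 and 1 with no background correction, 295 and 4 with normexp at offset 50, and 313 and 8 with the authors' values. With no normalization between arrays 197 genes were higher and 113 lower. That ratio of 1.74 exceeds the bound of 1.5 set beforehand, but lies so near it that scaling was left open. Its exact 95% interval of 1.38 to 2.22 spans the bound, though it takes genes as independent, which genes on the same arrays are not. Probes without a listed symbol were over-represented among the 351, at 48.7% against 29.3% of all tested (odds ratio 2.33, and 2.65 within 10 strata of level). Fisher's exact test gave p = 1.38e-14, which also takes genes as independent. A named gene entered by its brightest probe only (16302 kept probes, 12222 genes), while each of the 5075 probes without a symbol entered on its own. The odds ratio thus compares unlike units. RNA or DNA outside annotated genes may be a source, as a hypothesis. The design names no biological difference between replicate numbers, so no biological explanation was tested.

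KAT7 was not lower on the array labelled siHBO1 replicate 4. A control sample under a wrong label is argued against: the interferon list mean on that array lay 0.86 above the highest siCTRL array, where the siCTRL arrays had an SD of 0.44. Noise of a dim probe stays open: of 2835 genes of like intensity, 5.89% had some pair that departed as much (1.08) from the mean of the other pairs, above a bound of 5%. The share for pair 4 alone was 2.54%, under that bound, but that pair was picked for its departure. Both arrays of the pair contribute: the array labelled siHBO1 replicate 4 stood 0.57 above the mean of the other siHBO1 arrays, and siCTRL replicate 4 at -0.51 from the other siCTRL arrays. A weaker knockdown in the former and a low level in the latter also stay open and were not tested.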

How the results depend on the processing

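The replicate 2 to 4 and replicate 1 exclusions in both groups, and the authors' values with the block, were chosen after the data were seen. A slide block was not run, since the files name no slide, and detection at 0.01 on all arrays leaves out KAT7. The count of 6 genes was 16 with no background correction, 10 with normexp at offset 50, 0 at offset 1 (limma, 671 at an unadjusted p under 0.05) and 11 at offset 50. It was 0 with median scaling, with no normalization, with the authors' values and with every probe on its own (limma, 367, 169, 626 and 792 at an unadjusted p under 0.05), 18 with trend and robust, 68 with array weights (46 higher, 22 lower) and 0 at adjusted p under 0.01. Leaving out 1 array gave 0 to 5. Leaving out a replicate number in both groups gave 17 without replicate 1 and 0 without replicate 2, 3 or 4 (408, 424 and 524 unadjusted).

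With the replicate block the count was 58, as with the authors' values and the block (48 higher, 10 lower). It was 0 without replicate 2 or 3 (limma, 1068 and 1089 unadjusted), 33 without replicate 4 and 4 without replicate 1. Beyond the gene counts and the counts over single lists given in the report, the block changed no call of KAT7, nor of the 27 lists by camera or by fry in one direction. By fry in either direction, 2 lists passed without the block and 9 with it, and a call of the MHC class I genes changed too, as given with them. KAT7 lay between -1.01 and -0.33 in every setting that kept its probe. It passed in 1, the block without replicate 4 (-1.01, adjusted p = 0.0394), which removes the pair where KAT7 did not fall, so this is no evidence of the fall; over its settings adjusted p ran up to 1.00.

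The interferon list held its direction and its camera call in every setting with the preset correlation (median 0.97 to 1.30) and lost the call with an estimated correlation (1.18, adjusted p = 0.105). Its fry call was lost under the scalings and without the arrays named in the report, and with the block without replicate 1, 2, 3 or 4 in both groups (adjusted p = 0.105, 0.246, 0.241 and 0.201). Lists called were 3, 0 with an estimated correlation, 1 with fry, 1 to 4 without 1 array, 1 without replicate 4 in both groups and 1 with the block without replicate 2. The NF-kB list (0.12) lost its call with an estimated correlation and fry (adjusted p = 0.474 and 0.385), without replicate 3 (0.092) or 4 (0.12), and with the block without replicate 1 (0.13), 2 (0.12), 3 (0.092) or 4 (0.12); leaving out 1 array gave 0.061 to 0.13. The histone list (0.12) lost it with an estimated correlation and fry (0.657 and 0.567), without replicate 2 (0.082, block or not) or 4 (0.12), and leaving out 1 array gave 0.081 to 0.20. No result past the threshold reversed. Of the values of single named genes, 1994 kept their side of the threshold, 60 lost it and 78 gained it, and 679, 36 and 1 when 1 array was left out. The cause was not tested. Signal near background limits dim probes, KAT7 among them, whose fold shrinks to -0.33 without background correction.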

Other observations

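In this part the tests of leukocyte RNA, of the replicate 1 arrays, of the siRNA itself and of antigen presentation genes were chosen only after the result was seen. Genes that load peptides onto MHC class I stood higher in the siHBO1 group. A list of 17 tested members, written after the data were seen and so not independent evidence, had a median of 0.27 with 15 positive; TAP1, which carries peptides into the endoplasmic reticulum, the immunoproteasome subunit PSMB9 and the heavy chain HLA-B passed with the block at 0.81, 1.04 and 0.73, though another PSMB9 probe gave 0.45, and B2M stood at 0.03. Leaving out the members shared with the interferon list, 14 remained with a median of 0.17, 12 of them positive (camera p = 6.43e-06 with the preset correlation and p = 0.0524, above the threshold, with an estimated correlation). The block changed the calls of camera with an estimated correlation and of fry: the estimated-correlation value became 0.0449, and fry's value for the 14 genes in one direction 0.0181, against 0.0714 without it. They may move with the interferon response, as a hypothesis.

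Other genes that passed with the block, named here after their values were seen, were the interferon-induced GTPase genes GBP4 (0.78) and GBP5 (0.72). The same holds for the tryptophan-degrading enzyme gene IDO1 (1.08), USP18 (1.26) and the transcriptional regulator gene SP110 (0.87). IDO1 was detected on only 2 of the 4 siCTRL arrays, so the size of its rise is uncertain. Outside that family stood SPP1, which encodes osteopontin (0.94), the matrix proteoglycan gene VCAN (0.81), RASGRP3 (1.23) and CPA6 (0.77). RASGRP3 was detected on 3 of the 4 siCTRL arrays, so the size of its rise is uncertain too. No function beyond these descriptions was tested.

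The rise of the interferon list was set against 4 explanations. Scaling is argued against, since the lowest median over 7 other scalings, offsets and background corrections was 0.97; leukocyte RNA likewise, since 5 of 20 leukocyte markers (19 on the array) were detected on all 4 siHBO1 arrays, and the same 5, CD79A, CD14, CD68, CD74 and AIF1, on all 4 siCTRL arrays, with PTPRC, CD3E and LYZ on none. The replicate 1 arrays alone are argued against by the median of 1.07 without them. A response to the HBO1 siRNA apart from the fall of KAT7 cannot be told apart from an effect of KAT7: the list stood 0.94 higher in pair 4, where KAT7 was not lower, but that is 1 pair, and in the other pairs the siRNA and a lower KAT7 came together. That a lower KAT7 itself raises these genes stays open too.

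Other groupings of the arrays were compared with the real one. The numbers were taken as pairs, which the correlations bear out clearly for replicate 1 only. On that reading only the 8 splits that part every pair compare with the real one, and 8 are too few for a share under 0.05. A comparison with all 35 splits into 4 and 4 arrays, planned first, takes no account of the pairs. Among the 8, 1 split, the real one, gave as many as 6 genes, and the highest other gave 0. With the block the real one gave 58 genes and the highest other 0, and for lists the real one gave 3 and the highest other 2. Over all 35 splits every other split gave 0 genes, but 16 gave 3 or more lists, the highest 7. Apart from the real one these are the 15 that put both replicate 1 arrays on one side, which points to a structure of the samples. The interferon median was 1.18 in the real split and at most 0.88 in absolute size in any other.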
